A study of Homo sapiens with 18 samples.

How the data were processed

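Total RNA of MDA-MB-231 cells was sequenced 72 hours after lipofection of a control siRNA or of either of 2 siRNAs against RagC, with 500 ng of RNA per library per the labels. The authors deposited raw counts per gene in 1 table for the 18 libraries. Per the submitters' processing notes, reads were handled with cutadapt 0.6.2 and STAR 2.7.6a on GRCh37/hg19; the counting tool, the strand setting and the annotation release are not given in the sources used here. The table held 57820 gene identifiers, of which 51996 carried a symbol. Groups and replicate numbers were taken from the labels, and the code series (D1103 for numbers 1 and 2, D1221 for numbers 3 to 6) from the library codes; what the series stand for is not given in the sources used here. Totals ran from 14.8 M to 71.6 M counts per library. Between replicates of a group, the variance of counts summed over genes was between 2.88 and 81.6 times the counting variance. No library thus duplicated another of its group. The 81.6 came from siCtrl replicates 2 and 6, of different code series, and within a series the ratio reached 34.9 (siRagC1 replicates 3 and 4). Summed in this way, the spread between samples exceeded that from depth, which need not hold for genes of low count.

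Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr on group, robust quasi-likelihood F test), with a term for code series and a term for group over all 18 libraries. The filter left 15307 genes, 14845 of them with a name. The comparisons were siRagC1 against siCtrl, siRagC2 against siCtrl, siRagC1 against siRagC2, and the genes past the threshold in the same direction with both siRNAs. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, with no minimum fold. CPM values used TMM-scaled library sizes. These choices, the gene lists and the rule for named genes were written before the data were examined.

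The 27 gene lists held 837 genes, of which 828 were matched to the table and 768 tested; 9 symbols were not matched. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, and p was adjusted over the 27 lists. The text names genes by a rule in parts: RRAGC, its paralogs and the MiT/TFE factors; the 10 higher and 10 lower genes with the largest change past the threshold with both siRNAs and a mean of at least 5 CPM; 6 genes in each direction between the siRNAs, of which there were 0 because edgeR called none; and up to 4 members of each list. Genes outside the rule are marked as chosen after their values were seen. The result of 1 gene that the rule names is not reported here.

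Same-numbered libraries counted as possible pairs where every pair of residual profiles correlated above 0.1, and the main fit had no term for the number. This held for siCtrl with siRagC2 (0.116 to 0.492) and for siRagC1 with siRagC2 (0.221 to 0.582), and the count of calls with the number as a block is given beside the siRagC2 comparison. Between the siRNAs, edgeR with the block called 0 genes, with 1569 at an unadjusted p under 0.05. After the code series was removed these correlations ran from -0.144 to 0.302, and over all 3 pairings of groups a library's own number was the best match in 10 of 18 cases.

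The procedure was tested on simulated data made from the real counts, with 50 genes changed at each fold. The changed genes were drawn from genes with a mean count over 50 per library, so recovery at lower counts was not tested. Libraries were drawn independently within each code series, without the structure between the real libraries. The shares of unchanged genes among the calls can therefore be too low for the real data. edgeR recovered 48% and 52% of 1.2-fold changes in the comparisons with siRagC1 and siRagC2, 90% and 94% of 1.5-fold changes and 100% of 2-fold changes. Among its 176 and 184 calls, 7 and 11 were unchanged genes. Among 197 and 204 calls of DESeq2, 24 and 25 were unchanged, and its 1 call between the siRNAs was also an unchanged gene. Alternatives were RLE and upper-quartile factors; no filter and a filter of 5 CPM in 6 libraries; DESeq2 1.42.0; limma-voom; the replicate number as a block; no series term; a fit of the compared groups alone; each code series alone; each replicate number left out; an adjusted p under 0.01; a minimum fold of 1.2; and controls divided 3 and 3 between the comparisons. Chosen after seeing the data were each single library left out, effects fitted per code series, lists tested per series and, at both correlations, without siRagC1 replicate 4 or siCtrl replicate 6, the block together with the estimated correlation, and lists between the siRNAs per series. Reads, isoforms and protein were not analysed here.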

Results

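RNA was sequenced from MDA-MB-231, a human breast cancer cell line of the triple-negative type, 72 hours after transfection with siRNA. The study asked which genes change when mTORC1 is repressed, and silenced RagC to do so. mTORC1 is the kinase complex through which cells match growth to nutrients, and RagC, encoded by RRAGC, is a GTPase that pairs with RagA or RagB and tethers mTORC1 to the lysosome. A control siRNA (siCtrl) and 2 siRNAs against RagC (siRagC1 and siRagC2) were represented by 6 libraries each, 18 in all. The labels number the libraries of each group as biological replicates without saying whether they came from separate cultures or days, so p-values measure the spread between these samples. The library codes fell into 2 series, D1103 for replicates 1 and 2 of each group and D1221 for replicates 3 to 6. The libraries held between 14.8 M and 71.6 M counts, with medians of 21.4 M for siCtrl, 36.1 M for siRagC1 and 24.6 M for siRagC2. Of the 57820 genes listed, 15307 had enough counts to be tested.

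RRAGC (ENSG00000116954) fell with both siRNAs. It stood at 62.4 ± 2.75 CPM (counts scaled for library size; mean ± SD, n = 6) with siCtrl, at 23.9 ± 7.58 with siRagC1 and at 27.8 ± 8.30 with siRagC2, and was lower in all 6 same-numbered pairs of each comparison. The log2 fold change was -1.43 ± 0.17 (SE) with siRagC1 (edgeR, adjusted p = 0.000373) and -1.20 ± 0.17 with siRagC2 (adjusted p = 0.00135). In series D1103, RRAGC stood at 20.2% and 27.7% of the same-numbered control with siRagC1 and at 28.5% and 35.4% with siRagC2 (n = 2 each), against 45.6% ± 6.96 and 51.0% ± 12.3 (SD, n = 4 each) in D1221. Fitted per series, the fold changes were -2.04 ± 0.22 and -1.12 ± 0.15 for siRagC1 and -1.65 ± 0.21 and -0.95 ± 0.15 for siRagC2, and the difference between series had an adjusted p of 1.00 and 0.735 (unadjusted 0.00237 and 0.0141). With the D1221 libraries alone, the siRagC2 change of -0.95 missed the threshold (adjusted p = 0.0553).

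**Figure D1:**
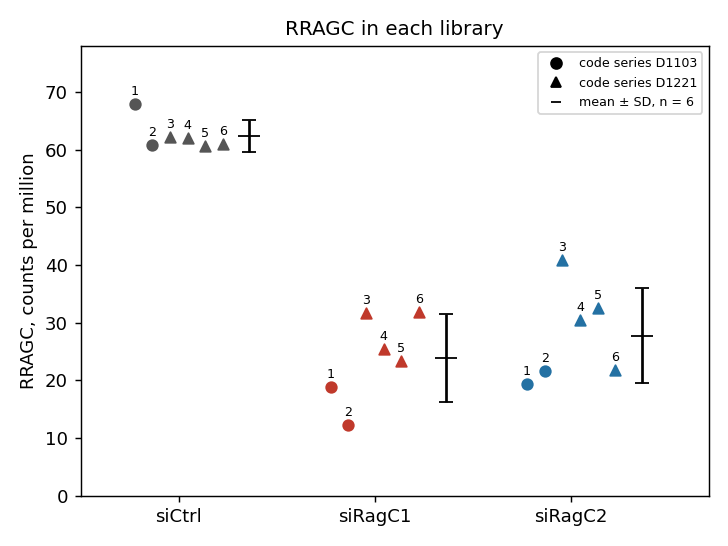
RRAGC in CPM (vertical axis) in each of the 18 libraries, numbered by replicate, with circles for code series D1103, triangles for D1221 and the mean ± SD of 6 libraries beside each group. Every siRagC1 and siRagC2 library lies below every siCtrl library, and the highest of them, siRagC2 replicate 3, reaches 40.8 CPM.

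The paralogs of RRAGC and the MiT/TFE transcription factors, which drive lysosomal genes and are held in the cytoplasm by mTORC1, mostly missed the threshold. RRAGA stood at 78.7 ± 3.53, 78.5 ± 4.01 and 79.7 ± 4.34 CPM with siCtrl, siRagC1 and siRagC2 (SD, n = 6). RRAGB had log2 fold changes of 0.19 ± 0.06 with each siRNA (SE, adjusted p = 0.0899 and 0.0742), and RRAGD of 0.42 ± 0.12 and 0.23 ± 0.12 (adjusted p = 0.0628 and 0.308). MITF fell with siRagC1 by 0.35 ± 0.07 (adjusted p = 0.0166), while its log2 fold change with siRagC2 was -0.19 ± 0.07 (adjusted p = 0.163). TFE3 had -0.14 ± 0.05 and -0.03 ± 0.05 (adjusted p = 0.180 and 0.837), TFEB 0.06 ± 0.09 and 0.04 ± 0.09 (adjusted p = 0.790 and 0.881), and TFEC had too few counts to be tested. As a list, the 3 tested factors were lower with siRagC1 by the camera test (mean log2 fold change -0.14, adjusted p = 0.0440; adjusted p = 0.264 with an estimated correlation) and had an adjusted p of 0.551 with siRagC2. MITF and TFE3 were lower with siRagC1 when adjusted over the list alone, and 0 factors with siRagC2. Without siRagC1 replicate 4 the siRagC1 list had an adjusted p of 0.0582 (mean -0.13), and it had 0.0487 in D1103 (mean -0.19; adjusted p = 0.436 with an estimated correlation) and 0.0755 in D1221 (mean -0.12).

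The comparison of siRagC1 with siCtrl asks what the first siRNA changed. ATP6V0D2, a subunit of the vacuolar proton pump, rose from 2.53 ± 0.946 to 6.71 ± 3.32 CPM (SD, n = 6; log2 fold change 1.36 ± 0.16, adjusted p = 0.000129), and NPC1, the lysosomal cholesterol exporter, from 200 ± 17.5 to 260 ± 20.9 CPM (0.38 ± 0.05, adjusted p = 0.000923). RAB27B, a GTPase of vesicle secretion, rose by 0.71 ± 0.12 (adjusted p = 0.00670), and SQSTM1, an autophagy receptor, by 0.56 ± 0.09 (adjusted p = 0.00236). ADAMTS1, a secreted metalloprotease, fell by 0.52 ± 0.12 (adjusted p = 0.0300), ITGA10, a collagen-binding integrin subunit, fell by 0.56 ± 0.11 (adjusted p = 0.0155), and IL11, a cytokine, fell by 0.69 ± 0.13 (adjusted p = 0.0155). Over all genes, 216 were higher and 96 lower with siRagC1. Among them, 8 higher genes and 1 lower gene, RRAGC, passed 2-fold, and the median absolute log2 fold change was 0.31. At an unadjusted p under 0.05 there were 2613 genes, against 765 by chance. The 765 is an average: genes vary together, so a count by chance can lie well away from it, here and below. With the D1103 libraries alone (n = 2 per group), 343 genes were higher and 211 lower. With the D1221 libraries alone (n = 4 per group), edgeR called 0 higher and 1 lower, RRAGC, with 997 genes at an unadjusted p under 0.05; limma-voom called 0 and 1, and DESeq2 23 and 3. Tested directly in edgeR, the effect of siRagC1 differed between the series for 0 genes, with 310 at an unadjusted p under 0.05 against 765 by chance. On simulated data this test recovered 0 of 50 genes with a 1.2-fold difference between the series and 19 of 50 with a 1.5-fold difference. The changed genes had a mean count over 50 per library, so genes with lower counts were not covered. Differences of the size of most called changes would mostly be missed. Single libraries also moved the counts by more than 1.5 times. Without siCtrl replicates 1, 2 or 5, in turn, 76, 79 and 129 genes were higher and 17, 24 and 47 lower. Without siRagC1 replicates 1, 2, 3, 4 or 6, in turn, 92, 66, 113, 135 and 522 were higher and 26, 12, 35, 49 and 371 lower. The count of lower genes alone moved to 153, 186 and 46 without siCtrl replicate 3, siCtrl replicate 6 and siRagC1 replicate 5.

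The comparison of siRagC2 with siCtrl asks the same of the second siRNA. SLC2A3, a glucose transporter, rose from 78.1 ± 6.20 to 122 ± 42.2 CPM (SD, n = 6; log2 fold change 0.60 ± 0.12, adjusted p = 0.0107). COL16A1, a collagen chain, rose by 0.67 ± 0.15 (adjusted p = 0.0175), CSF1, a macrophage growth factor, by 0.44 ± 0.09 (adjusted p = 0.0104), and ICAM1, an adhesion receptor, by 0.43 ± 0.09 (adjusted p = 0.0110). PSAT1, an enzyme of serine synthesis, fell from 86.8 ± 6.67 to 64.2 ± 10.8 CPM (-0.45 ± 0.06, adjusted p = 0.000396), and MARS1, a tRNA synthetase, fell by 0.23 ± 0.04 (adjusted p = 0.00715). Over all genes, 287 were higher and 208 lower with siRagC2, of which 10 higher genes and 1 lower gene, RRAGC, passed 2-fold, with a median absolute log2 fold change of 0.28. At an unadjusted p under 0.05 there were 2833 genes, against 765 by chance. With the replicate number as a block, 560 genes were higher and 426 lower. With the D1103 libraries alone (n = 2 per group), 618 were higher and 531 lower. With the D1221 libraries alone (n = 4 per group), edgeR called 1 higher, PIM1, a gene chosen after its values were seen (0.54 ± 0.07, adjusted p = 0.0114), and 0 lower, with 1420 genes at an unadjusted p under 0.05; limma-voom called 2 and 1, and DESeq2 39 and 19. The effect of siRagC2 differed between the series for 0 genes in edgeR, with 1019 at an unadjusted p under 0.05 against 765 by chance; the same test, simulated for siRagC1, missed all 50 differences of 1.2-fold and recovered 19 of 50 of 1.5-fold. Without siCtrl replicates 1 or 2, in turn, 127 and 162 genes were higher and 70 and 128 lower. Without siRagC2 replicates 1 or 4, in turn, 129 and 125 were higher and 72 and 82 lower, and without siRagC2 replicate 2, 127 were lower.

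Genes that passed the threshold with both siRNAs address what is shared between 2 sequences with 1 target. SULT1C2, a sulfotransferase, rose from 3.93 ± 0.517 CPM with siCtrl to 6.66 ± 1.38 and 7.06 ± 2.00 (SD, n = 6; log2 fold changes 0.77 ± 0.12 and 0.82 ± 0.12, adjusted p = 0.00174 and 0.00107). GDF15, a stress-induced cytokine, rose by 0.69 ± 0.17 and 0.81 ± 0.17, BMF, a proapoptotic BH3 protein, by 0.66 ± 0.14 and 0.96 ± 0.15, and KLHL24 by 0.55 ± 0.09 and 0.58 ± 0.09. SHC2, TTC39A, PADI1, SLC14A1, HKDC1 and MEGF6 completed the 10 named higher genes, with log2 fold changes between 0.48 and 0.81. Apart from RRAGC, the named lower genes were IL11 (-0.69 ± 0.13 and -0.52 ± 0.13), MPP4, ARG2, ZNF804A, MCM10, RGMB (229 ± 17.7 CPM with siCtrl, 182 ± 19.4 and 184 ± 10.7 with the siRNAs), AOX1, PSAT1 and CDC6, with log2 fold changes between -0.69 and -0.30. In all, 118 genes were higher and 48 lower with both siRNAs, and 0 went in opposite directions. The comparisons used the same 6 controls, which favours equal signs and shared calls. With the 6 controls divided between the comparisons, 4 and 1 genes were shared in one division and 6 and 2 in the reverse, where siRagC1 had 5 and 56 calls and siRagC2 141 and 24.

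Across the 15307 genes, the fold changes of the siRNAs had a Pearson correlation of 0.687 and a covariance of 0.0210; genes are not independent replicates. In 50 simulations of unchanged groups, the shared controls gave a correlation of 0.533 (0.514 to 0.555) and a covariance of 0.00866 (0.00810 to 0.00918). The simulated libraries were drawn independently within each code series. They lacked the structure between the real libraries, so these ranges can be too narrow. With the controls divided, the correlations were 0.314 and 0.338 and the covariances 0.0125 and 0.0132. With the replicate number as a block, 278 genes were higher and 173 lower with both siRNAs. With D1103 alone, 175 were higher and 114 lower with both. With D1221 alone, edgeR gave 0 and 0. Without siCtrl replicates 1, 2 or 5, in turn, 43, 53 and 69 genes were higher with both siRNAs and 6, 13 and 23 lower. Without siRagC1 replicates 1, 2 or 3, in turn, 66, 55 and 74 were higher and 16, 8 and 21 lower, and without siRagC2 replicates 1 or 4, 69 and 72 were higher and 25 and 22 lower. The count of lower genes alone moved to 77 and 78 without siCtrl replicates 3 and 6, and to 26 and 85 without siRagC1 replicates 5 and 6.

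**Figure D2:**
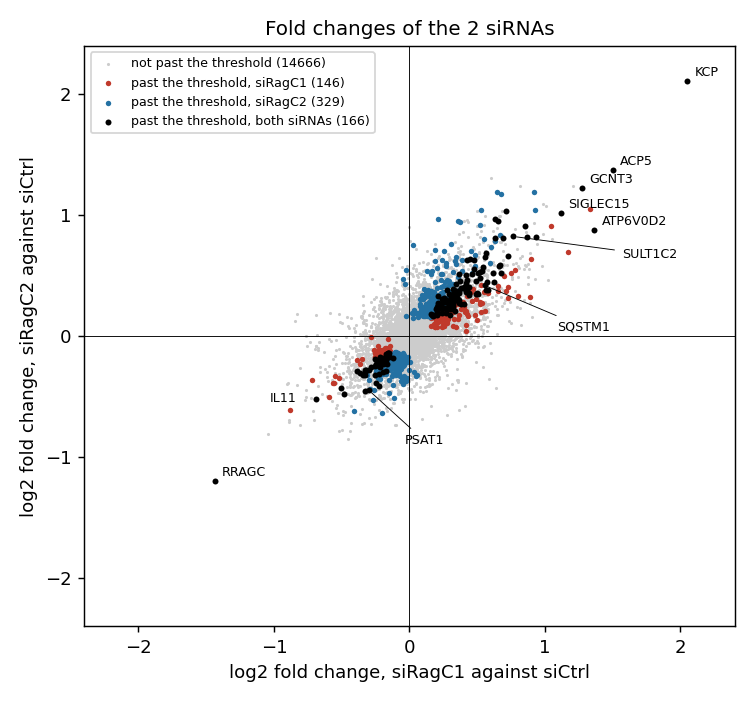
Log2 fold changes of the 15307 tested genes with siRagC1 (horizontal axis) and siRagC2 (vertical axis) against the same siCtrl libraries; black points passed the threshold with both siRNAs (166), red with siRagC1 (146), blue with siRagC2 (329) and grey with neither. The 166 black points lie in the quadrants where both changes have the same sign; KCP, ACP5, GCNT3 and SIGLEC15 are low-count genes labelled after their values were seen.

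Genes of lysosomal enzymes and membrane proteins rose together with both siRNAs. Of the 49 measured members, 19 were higher and 0 lower with siRagC1, and 18 were higher and 1 lower with siRagC2 (ARSB, -0.24, adjusted p = 0.0295, chosen after its values were seen). ASAH1, the acid ceramidase, rose by 0.34 ± 0.05 and 0.32 ± 0.06 (SE; adjusted p = 0.00236 and 0.00352), NEU1, a sialidase, by 0.33 ± 0.07 and 0.38 ± 0.07 (adjusted p = 0.0124 and 0.00411), and CTSL, a cysteine protease, by 0.29 ± 0.04 and 0.22 ± 0.04 (adjusted p = 0.00174 and 0.00963). NPC1 rose by 0.38 ± 0.05 and 0.27 ± 0.05 (adjusted p = 0.000923 and 0.0104). The mean log2 fold change of the list was 0.18 with siRagC1 and 0.17 with siRagC2, and 45 of 49 members had a positive value with each. In all, 31 members adjusted over the list alone were higher with siRagC1, and 30 higher and 1 lower with siRagC2. The camera test with a preset correlation gave adjusted p = 5.31e-20 and 5.91e-17, and adjusted p = 0.0240 and 0.0328 with an estimated correlation. In series D1103 the mean was 0.25 and 0.17 (adjusted p = 5.56e-19 and 6.42e-10) and in D1221 it was 0.15 and 0.16 (adjusted p = 1.37e-15 and 6.44e-15); with an estimated correlation the adjusted p was 0.203 and 0.414 in D1103, and 0.126 and 0.0969 in D1221. Without any single library the mean stayed between 0.17 and 0.21 with siRagC1 and between 0.15 and 0.18 with siRagC2. The adjusted p with an estimated correlation was over 0.05 without siCtrl replicate 6 for siRagC1 (0.0514, mean 0.17), and without siCtrl replicate 6 (0.0529, mean 0.15) or siRagC2 replicates 3, 5 or 6 (0.0589, 0.0510 and 0.0558, means 0.16, 0.17 and 0.17) for siRagC2.

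**Figure D3:**
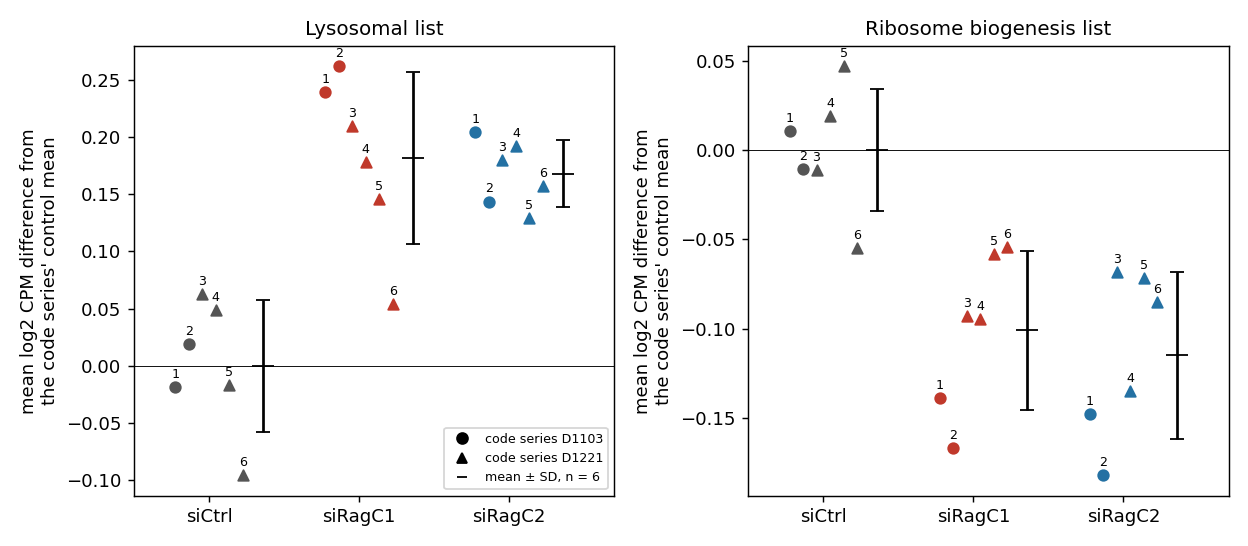
Mean log2 CPM difference of each library from the siCtrl mean of its code series (vertical axis) over the 49 lysosomal genes (left) and the 34 ribosome biogenesis genes (right), numbered by replicate, with circles for D1103, triangles for D1221 and the mean ± SD of 6 libraries beside each group. In the lysosomal list the siRagC1 libraries lie between 0.054 and 0.262 and the siRagC2 libraries between 0.129 and 0.204, and siCtrl replicate 6 is the lowest at -0.0956.

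Ribosome biogenesis genes fell together. As written, their list held nucleolar factors that process ribosomal RNA, and also genes that transcribe it, such as POLR1A and UBTF, and MYC. Of 34 measured members, 6 were lower with siRagC1 and 5 with siRagC2, and 0 were higher with either; adjusted over the list alone, 18 and 16 were lower. UTP4 fell by 0.18 ± 0.04 and 0.22 ± 0.04 (adjusted p = 0.0321 and 0.00847), NOP58 by 0.16 ± 0.04 and 0.23 ± 0.04 (adjusted p = 0.0433 and 0.00468), NOP16 by 0.22 ± 0.05 and 0.20 ± 0.05, and GNL3 by 0.15 ± 0.04 and 0.14 ± 0.04. WDR43, chosen after its values were seen, was the fifth lower gene with siRagC2 (-0.16, adjusted p = 0.0295). The list's mean was -0.10 and -0.12 (camera adjusted p = 4.57e-11 and 6.68e-12; adjusted p = 0.0240 and 0.0181 with an estimated correlation). In D1103 the mean was -0.15 and -0.17 (adjusted p = 1.47e-09 and 9.07e-09) and in D1221 -0.08 and -0.09 (adjusted p = 5.41e-08 and 7.27e-08); with an estimated correlation the adjusted p was 0.203 and 0.414 in D1103 and 0.103 and 0.0969 in D1221. Cytosolic ribosomal proteins had 0 members past the threshold in edgeR with either siRNA, also adjusted over the list alone. Their mean was 0.045 with siRagC1 (adjusted p = 5.14e-05; adjusted p = 0.527 with an estimated correlation) and -0.0059 with siRagC2 (adjusted p = 0.551). For siRagC2 the mean was -0.080 in D1103 (adjusted p = 3.56e-06) and 0.032 in D1221 (adjusted p = 0.107), and for siRagC1 it was 0.0048 (adjusted p = 0.846) and 0.065 (adjusted p = 5.38e-09). With an estimated correlation the adjusted p was 0.475 for siRagC2 in D1103 and 0.373 for siRagC1 in D1221.

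The members of the cell cycle and amino acid response lists that passed the threshold were lower with both siRNAs or with siRagC2. Of 53 cell cycle genes, the replication factors MCM10 and CDC6 were lower with siRagC1 (-0.33 ± 0.08 and -0.32 ± 0.08), and these together with PCNA, MCM6 and CCNE2 were lower with siRagC2 (-0.32, -0.30, -0.24, -0.27 and -0.37; CCNE2 was chosen after its values were seen). In this list 7 and 5 were lower when adjusted over the list alone. The list's mean was -0.12 and -0.10 (adjusted p = 4.86e-10 and 7.86e-06; adjusted p = 0.483 and 0.726 with an estimated correlation). In D1103 it was -0.19 and -0.20 (adjusted p = 5.56e-19 and 4.10e-13; 0.332 and 0.475 with an estimated correlation), and in D1221 it was -0.09 and -0.05 (adjusted p = 5.03e-06 and 0.0792; 0.679 and 0.850 with an estimated correlation). Of 33 genes of the ATF4 and amino acid response, PSAT1, MARS1, MTHFD2 and GARS1 were lower with both siRNAs, by between 0.15 and 0.45 in absolute log2 value, and ASNS, MTHFD1L and AARS1, chosen after their values were seen, also with siRagC2 (-0.31, -0.21 and -0.20). Adjusted over the list alone, 5 and 16 were lower, and the mean was -0.055 and -0.10 (adjusted p = 6.14e-05 and 2.32e-08; adjusted p = 0.381 and 0.203 with an estimated correlation). In D1103 it was -0.10 and -0.18 (adjusted p = 1.85e-05 and 9.07e-09; 0.332 and 0.414 with an estimated correlation) and in D1221 -0.03 and -0.05 (adjusted p = 0.00407 and 0.000162; 0.594 and 0.662 with an estimated correlation). The 42 genes of the mTORC1 nutrient-sensing pathway included FLCN and FNIP1, which act on RagC as a GTPase-activating complex. FLCN rose by 0.23 ± 0.05 with each siRNA and FNIP1 by 0.32 ± 0.06 and 0.25 ± 0.06, and besides RRAGC, SESN1, a stress-induced inhibitor of the pathway, fell with siRagC2 by 0.51 (adjusted p = 0.0259, chosen after its values were seen). Adjusted over the list alone, 6 were higher and 1 lower with siRagC1, and 4 and 4 with siRagC2. The list had an adjusted p of 0.0541 and 0.239.

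In the endolysosomal lists beside the enzymes, single members stood out. Of 17 vacuolar ATPase subunits, ATP6V0D2 rose by 1.36 ± 0.16 and 0.87 ± 0.16, and ATP6V0A2, chosen after its values were seen, fell with siRagC2 by 0.18 (adjusted p = 0.0334). ATP6V1F, ATP6AP1 and ATP6V0E1 had log2 fold changes between 0.10 and 0.15. The list's mean was 0.14 and 0.080 (adjusted p = 0.00294 and 0.199; adjusted p = 0.105 with an estimated correlation for siRagC1), and 3 members were higher with each siRNA and 1 lower with siRagC2 adjusted over the list alone. Of 42 autophagy genes, SQSTM1 rose from 698 ± 142 CPM to 1036 ± 252 and 934 ± 184 (0.56 ± 0.09 and 0.42 ± 0.09), and MAP1LC3A, chosen after its values were seen, and ATG2A rose with siRagC2 (0.54 and 0.24). Adjusted over the list alone, 1 and 5 were higher, and the list had an adjusted p of 0.240 with siRagC1 and 0.00997 with siRagC2 (adjusted p = 0.178 with an estimated correlation, and 0.0440 when the replicate number was also a block). With siRagC2 its mean was 0.12 in D1103 (adjusted p = 0.00832; 0.475 with an estimated correlation) and 0.075 in D1221 (adjusted p = 0.0792). Of 39 genes of lysosome positioning and exocytosis, 6 were higher with siRagC1, among them RAB27B, RILP (0.35 ± 0.08) and WASHC2C (0.20 ± 0.05), and BLOC1S2, chosen after its values were seen, was lower with siRagC2 (-0.24, adjusted p = 0.0415). When adjusted over the list alone, 9 were higher with siRagC1, and 2 higher and 1 lower with siRagC2. The list had an adjusted p of 0.00634 (adjusted p = 0.162 with an estimated correlation) and 0.224.

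Genes of the extracellular matrix and its turnover included members that moved both ways. Of 33 matrix proteases and inhibitors, TIMP2, an inhibitor of metalloproteases, rose from 555 ± 21.5 CPM to 644 ± 27.5 and 671 ± 36.0 (0.21 ± 0.03 and 0.27 ± 0.03, adjusted p = 0.00240 and 0.000396). MMP15, chosen after its values were seen, rose with siRagC1 (0.52, adjusted p = 0.0488) while ADAMTS1 fell, and MMP11 (0.63 ± 0.16, adjusted p = 0.0370) and the protease inhibitor SERPINE2, chosen after its values were seen (0.19, adjusted p = 0.0175), rose with siRagC2. DPP4 had 0.39 ± 0.11 and 0.35 ± 0.12 (adjusted p = 0.0706 and 0.101). Adjusted over the list alone, 6 were higher and 1 lower with siRagC1 and 5 and 1 with siRagC2. The list's mean was 0.10 and 0.12 (adjusted p = 0.0391 and 0.00365; adjusted p = 0.162 and 0.0328 with an estimated correlation), and without siCtrl replicate 6 the siRagC1 value was 0.0658 (mean 0.09) and the siRagC2 value with an estimated correlation 0.0529 (mean 0.11). The mean was 0.14 and 0.14 in D1103 (adjusted p = 0.0392 and 0.0504) and 0.079 and 0.12 in D1221 (adjusted p = 0.0828 and 0.00637), with an adjusted p between 0.0969 and 0.475 with an estimated correlation. Of 42 structural matrix proteins, LAMA3 rose (0.32 ± 0.07) and COL8A1 fell (-0.21 ± 0.05) with siRagC1. COL16A1 and, chosen after their values were seen, COL1A1, TGFBI and LOX rose with siRagC2 (0.67, 0.75, 0.54 and 0.36). Adjusted over the list alone, 3 were higher and 2 lower, then 14 and 3. The list had an adjusted p of 0.0807 with siRagC1 and 0.0159 with siRagC2 (adjusted p = 0.650 with an estimated correlation), and the latter was 0.159 without siCtrl replicate 6. With siRagC2 its mean was 0.19 in D1103 (adjusted p = 6.62e-05; 0.475 with an estimated correlation) and 0.066 in D1221 (adjusted p = 0.346). Of 15 integrins, ITGA10 fell with siRagC1, ITGB5 had 0.20 ± 0.06 and 0.17 ± 0.06, and 4 were higher and 1 lower, then 3 and 1, adjusted over the list alone (adjusted p of the list 0.0562 and 0.199). None of 27 invadopodia and actin genes passed the threshold in edgeR with either siRNA, also adjusted over the list alone (SH3PXD2B 0.26 ± 0.10 and 0.25 ± 0.10; list adjusted p = 0.412 and 0.780). Of 19 genes of mesenchymal and epithelial state, CLDN7, a tight junction protein, rose with siRagC2 (0.27 ± 0.06, adjusted p = 0.0211), also adjusted over the list alone, and the list had an adjusted p of 0.831 and 0.551.

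The remaining lists held few called members. Of 34 interferon-stimulated genes, IFIH1, a sensor of double-stranded RNA, rose with siRagC1 (0.42 ± 0.08, adjusted p = 0.0124; 4 higher adjusted over the list alone), and 0 passed in edgeR with siRagC2; the list's mean was 0.12 and 0.0070 (adjusted p = 0.00269 and 0.847; adjusted p = 0.397 with an estimated correlation for siRagC1). With siRagC1 its mean was 0.20 in D1103 (adjusted p = 6.67e-06; 0.340 with an estimated correlation) and 0.072 in D1221 (adjusted p = 0.0980). EDEM1, of 21 unfolded protein response genes, rose with siRagC1 (0.18 ± 0.04; list adjusted p = 0.953 and 0.635). Of 30 glycolysis and hypoxia genes, SLC2A3 and CA12 rose with siRagC2 (0.60 ± 0.12 and 0.28 ± 0.06; list adjusted p = 0.423 and 0.835), and the siRagC1 list had 0.0384 without siCtrl replicate 6 (adjusted p = 0.617 with an estimated correlation). With siRagC2 the glycolysis mean was 0.16 in D1103 (adjusted p = 0.00279; 0.640 with an estimated correlation) and -0.0080 in D1221 (adjusted p = 0.476). Of 20 p53 targets and cell cycle inhibitors, CDKN1B, chosen after its values were seen, rose with siRagC2 (0.30, adjusted p = 0.00185) and SESN1 fell (list adjusted p = 0.537 and 0.949). Of 22 NF-kB and cytokine genes, NFKB1 fell with siRagC1 (-0.14 ± 0.04) and CSF1 and ICAM1 rose with siRagC2 (list adjusted p = 0.687 and 0.780). Adjusted over each list alone, the unfolded protein, glycolysis, p53 and NF-kB lists had 1, 1, 0 and 1 higher and 0, 1, 0 and 1 lower genes with siRagC1, and 0, 2, 3 and 2 higher and 0, 0, 3 and 0 lower with siRagC2. In edgeR, 0 members passed with either siRNA among 25 cholesterol, 18 fatty acid and 44 nuclear oxidative phosphorylation genes (list adjusted p = 0.171 and 0.801, 0.432 and 0.563, and 0.276 and 0.551). STARD4 had -0.16 ± 0.07 and -0.20 ± 0.07, SCD5 -0.08 ± 0.05 and -0.19 ± 0.05, and NDUFA8 0.11 ± 0.04 and 0.07 ± 0.04. Adjusted over these lists alone, 1 member was called, SCD5, lower with siRagC2. With siRagC1, the cholesterol list had an adjusted p of 0.0460 without siRagC1 replicate 4 and 0.00591 without siCtrl replicate 6 (adjusted p = 0.754 and 0.588 with an estimated correlation). The 15 mitochondrial transcripts also had 0 called members (list adjusted p = 0.0391 with siRagC1, 0.668 with an estimated correlation, and 0.847 with siRagC2). Mitochondrial transcripts took 2.55% of the counts in siRagC1 replicate 4 and between 4.08% and 6.63% elsewhere, and without that library the siRagC1 list mean moved from -0.079 to 0.014 (adjusted p = 0.826). Without siCtrl replicate 6 the mean was -0.082 and the adjusted p 0.0693. With siRagC1 the mitochondrial mean was 0.020 in D1103 (adjusted p = 0.846) and -0.13 in D1221 (adjusted p = 0.000778; 0.623 with an estimated correlation). Lists past the threshold in D1103 and neither in D1221 nor over all libraries were, with siRagC1, the autophagy, mTORC1, cholesterol, matrix structural and integrin lists (means 0.081, 0.044, -0.056, 0.11 and 0.065; adjusted p = 0.0392, 0.0392, 0.0417, 0.0392 and 0.0184) and, with siRagC2, the glycolysis, nuclear oxidative phosphorylation and cytosolic ribosomal protein lists (the second with mean -0.051, adjusted p = 0.0274). With an estimated correlation their adjusted p in D1103 lay between 0.332 and 0.665.

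Markers of other cells gave little signal. Of 12 luminal markers, 0 passed in edgeR (XBP1 -0.06 ± 0.04 and -0.07 ± 0.04; list adjusted p = 0.786 and 0.914), as did 0 of 5 leukocyte markers (CSF1R 0.06 ± 0.08 and 0.09 ± 0.08; list adjusted p = 0.412 and 0.661). Of 6 fibroblast and endothelial markers, COL1A1 was higher with siRagC2 (KDR 0.22 ± 0.10 and 0.32 ± 0.10; list adjusted p = 0.691 and 0.228). Adjusted over these lists alone, 1 leukocyte marker, LYZ, was lower with siRagC1 (-1.04 ± 0.34), and 2 fibroblast and endothelial markers, COL1A1 and KDR, were higher with siRagC2. The mean and the median of a list differed in sign in the leukocyte (-0.26 and 0.024), fatty acid, unfolded protein, glycolysis and NF-kB lists with siRagC1, and in the cholesterol, unfolded protein, interferon, NF-kB and luminal lists with siRagC2. In the mesenchymal and epithelial list they differed with both.

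**Figure D4:**
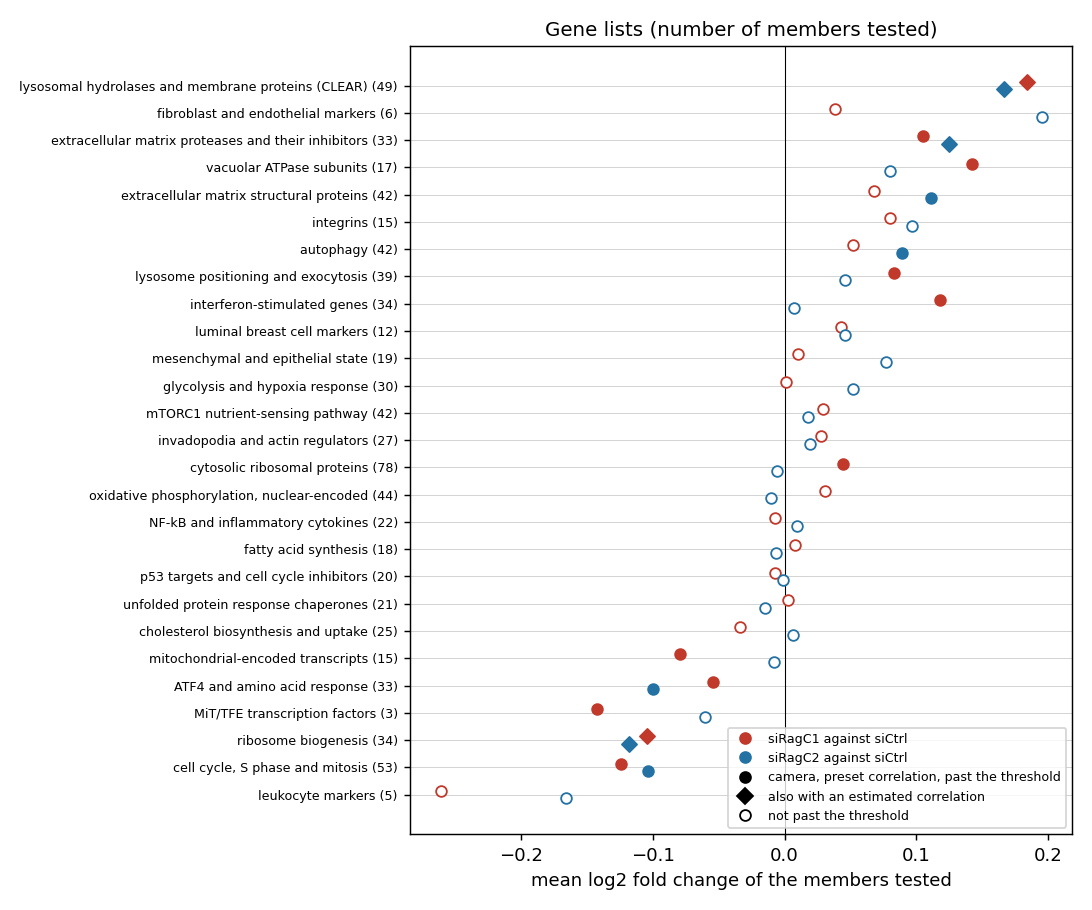
Mean log2 fold change (horizontal axis) of the tested members of each of the 27 gene lists (vertical axis, with the number of members) with siRagC1 (red) and siRagC2 (blue) against siCtrl; filled marks passed the camera test with a preset correlation, diamonds also with an estimated correlation, and open circles neither. The lysosomal list stands at 0.18 and 0.17 and the ribosome biogenesis list at -0.10 and -0.12.

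The comparison of siRagC1 with siRagC2 asks where the siRNAs differ. RRAGC differed by -0.23 ± 0.17 in log2 (SE, n = 6; adjusted p = 0.792), and the 49 lysosomal genes by a mean of 0.017 (camera adjusted p = 0.459). The lysosomal difference was 0.077 in D1103 (adjusted p = 0.00800; 0.648 with an estimated correlation) and -0.016 in D1221 (adjusted p = 0.527). ATP6V0D2 had the smallest unadjusted p among the named genes, with a difference of 0.49 ± 0.14 (adjusted p = 0.370), and RAB27B differed by 0.34 ± 0.12 (adjusted p = 0.482). In edgeR, 0 genes were higher and 0 lower, with 1187 at an unadjusted p under 0.05 against 765 by chance and a smallest adjusted p of 0.271. limma-voom also called 0, and DESeq2 called 18 higher and 11 lower with siRagC1. Cytosolic ribosomal proteins (mean 0.051, adjusted p = 2.12e-11), interferon-stimulated genes (0.11, adjusted p = 1.96e-05), nuclear oxidative phosphorylation genes (0.041, adjusted p = 0.0197) and ATF4 response genes (0.045, adjusted p = 0.0284) were higher with siRagC1, and mitochondrial transcripts lower (-0.071, adjusted p = 0.0284). With an estimated correlation the adjusted p of these lists was 0.418, 0.418, 0.418, 0.792 and 0.794, and adjusted over the list alone 5 interferon-stimulated genes were higher with siRagC1. In D1103 the ribosomal protein, interferon, oxidative phosphorylation and ATF4 lists differed by 0.085, 0.21, 0.066 and 0.079 (adjusted p = 2.32e-09, 6.16e-08, 0.00800 and 0.00649; 0.648 each with an estimated correlation). In D1221 they differed by 0.033, 0.052, 0.028 and 0.027 (adjusted p = 4.88e-05, 0.0562, 0.162 and 0.141; 0.601 for the first with an estimated correlation). Without siRagC1 replicate 4, the oxidative phosphorylation and ATF4 lists had an adjusted p of 0.0693 and 0.0594 (differences of 0.034 and 0.034). Also past the threshold within a series were, in D1103, the glycolysis, NF-kB, matrix structural and lysosome positioning lists (-0.14, -0.091, -0.083 and 0.080; adjusted p = 2.96e-05, 0.00328, 0.0227 and 0.0282; 0.648 to 0.772 with an estimated correlation) and, in D1221, the cell cycle list (-0.034, adjusted p = 0.0375; 0.927 with an estimated correlation). Without siRagC1 replicate 4, where mitochondrial transcripts took 2.55% of the counts against 4.08% to 6.63% elsewhere, the mitochondrial list differed by 0.022 (adjusted p = 0.524). Without siCtrl replicate 6 it differed by -0.071 (adjusted p = 0.0574), and the difference was 0.046 in D1103 (adjusted p = 0.458) and -0.13 in D1221 (adjusted p = 0.000220; adjusted p = 0.601 with an estimated correlation). The count of genes depended on replicate 6: without its 3 libraries, 290 genes were higher and 229 lower with siRagC1; without siRagC1 replicate 6 alone, 51 and 27; and without siRagC2 replicate 6 alone, 18 and 13. With D1103 alone (n = 2 per group), 134 were higher and 97 lower; with D1221 alone (n = 4 per group), edgeR, limma-voom and DESeq2 each called 0, with 365, 273 and 391 genes at an unadjusted p under 0.05. The difference between the siRNAs differed between the series for 0 genes in edgeR, with 586 at an unadjusted p under 0.05 against 765 by chance, in a test that recovered 0 of 50 simulated 1.2-fold differences for siRagC1.

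**Figure D5:**
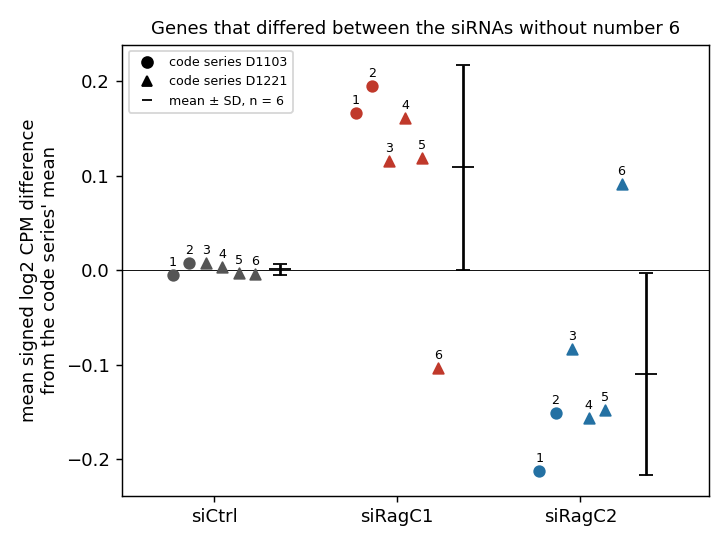
Mean signed log2 CPM difference from the mean of all libraries of the same code series (vertical axis) over the genes that differed between siRagC1 and siRagC2 without replicate 6, in each library, numbered by replicate; genes higher with siRagC1 count as positive, and the mean ± SD of 6 libraries stands beside each group. Replicates 1 to 5 separate by construction, since they chose the genes, while siRagC1 replicate 6 lies at -0.104 and siRagC2 replicate 6 at 0.0916.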

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

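The tests of controls shared by the comparisons, of comparisons on separate replicate numbers, of MiT/TFE targets, of exchanged labels and of a control library under the siRagC1 label were chosen only after the results were seen. In 84 groups of 6 libraries, 6 had a library further from the rest than Dixon's test allows, where chance gives about 1 in 20 groups, or 4.2. RRAGC stood at 67.9 CPM in siCtrl replicate 1 against 60.6 to 62.2 in the other controls. RRAGA stood at 72.0 CPM in siCtrl replicate 6 against 78.8 to 81.8. TTC39A stood at 8.34 CPM in siRagC2 replicate 1 against 4.76 to 5.89. ARG2 stood at 33.0 CPM in siCtrl replicate 1 against 22.8 to 25.4. MCM10 stood at 46.3 CPM in siRagC1 replicate 6 against 31.6 to 36.7. CDC6 stood at 73.0 CPM in siRagC2 replicate 5 against 58.0 to 61.8.

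The fold changes were shared by both siRNAs, with 166 genes past the threshold in the same direction. With the controls divided between the comparisons, the lower covariance was 0.01105 by least squares, where simulated unchanged groups of independent libraries reached at most 0.000671, which argues against common controls alone. With siRagC1 compared on numbers 1, 3 and 5 and siRagC2 on numbers 2, 4 and 6, and the reverse, no control and no number was common, and the lower covariance of 0.0106 was reached by 1 of 100 relabellings within the numbers, the real one (highest other 0.00711), which argues against likeness of same-numbered libraries as the whole source. Relabelling all libraries gave a covariance as high in 2 of 100 cases, the real one included (highest other 0.0293), and as many shared genes in 1 of 100, the real one (highest other 0). The siCtrl libraries also received an siRNA by lipofection, so an effect of transfection alone is in both sides of each comparison. An effect of silencing RRAGC and an effect of both RagC siRNAs that is unrelated to RRAGC and absent with siCtrl could both give shared changes. No library of this series tells these 2 apart.

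Lysosomal genes rose with both siRNAs. Of 10000 random lists matched on expression, 0 had a mean as high with either siRNA, which argues against a trend with expression level. A single library did not account for it at the preset correlation, where the highest adjusted p without any 1 library was 3.627e-15, and the mean log2 fold change stayed between 0.17 and 0.21 with siRagC1 and between 0.15 and 0.18 with siRagC2, while the adjusted p with an estimated correlation rose over 0.05 without siCtrl replicate 6 with siRagC1 (0.0514) and in 4 of 18 cases with siRagC2 (siCtrl replicate 6, 0.0529; siRagC2 replicates 3, 5 and 6, 0.0589, 0.0510 and 0.0558). A candidate explanation is raised activity of MiT/TFE factors: 14 textbook targets outside the list, chosen after the result was seen, had a mean log2 fold change of 0.29 and 0.22 (larger camera p 0.001672 with an estimated correlation). These targets were chosen with the results known and kept apart from the lysosomal list alone, so they are no independent test. Protein activity and location were not measured, and raised MiT/TFE activity stays a hypothesis.

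siRagC1 and siRagC2 replicate 6 stood apart from the other numbers. Of the 519 genes that differed between the siRNAs without number 6, 518 also passed the filter with all libraries. Of these, 461 (89%) had the opposite sign in the number 6 pair. This fell short of the bound of over 90 set for exchanged labels and lay above the bound of 50 set against them. The upper bound could not decide. Over the 500 genes with the smallest p without each number in turn, 16.2% to 19.2% had the opposite sign in numbers 1 to 5, against 88.8% in number 6. Pairs 1 to 5 were thus never fully of the same sign, so an exchanged pair need not pass 90. Exchanged labels stay open. RRAGC was lower with siRagC1 than with siRagC2 in numbers 1 to 5 (20.2% to 51.0% against 28.5% to 65.6% of the same-numbered control) and higher in number 6 (52.2% against 35.8%). A weaker knock-down in siRagC1 replicate 6 would leave genes whose difference ran against their mean change in place, yet 87.88% of these were opposite too, and a control library under its label is argued against by RRAGC at 52.19% of siCtrl replicate 6. The groups were kept as labelled, and the 290 and 229 genes that differ without number 6 are therefore a result on 5 libraries per group; with the number 6 labels of the siRNAs exchanged, siRagC1 gave 506 higher and 381 lower genes (216 and 96 as labelled), siRagC2 359 and 295 (287 and 208), and both together 156 and 77 (118 and 48). No biological explanation other than the strength of the knock-down was tested.

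For siRagC1 against siCtrl, 2 of 100 splits of the libraries, the real one included, gave as many genes (312; highest other 650, in the split that exchanged siRagC1 replicate 6 with siCtrl replicate 4, which points to a structure of the samples). For siRagC2 against siCtrl, the real split alone did so, 1 of 100 (495; highest other 3), as it did among the 32 splits that part every same-numbered pair, 1 of 32 (highest other 31). For siRagC2 both shares lay under 0.05, which argues against chance. Only the 32 pair-parting splits kept the code series balanced, and 1 of 32 is the smallest share they can give. For siRagC1 the share of 2 of 100 also lay under 0.05, but a split other than the real one called more genes. The 100 splits of each comparison were drawn without keeping the code series balanced, so chance is not excluded for siRagC1. For siRagC1 against siRagC2, edgeR called 0 genes (1187 at an unadjusted p under 0.05; limma-voom 0, DESeq2 18 and 11), so that 100 of 100 splits and 32 of 32 pair-parting splits had to give as many, which says nothing about chance; the highest of the latter, 332, exchanged the number 6 libraries.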

How the results depend on the processing

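Single libraries left out, effects per code series and list tests per series were chosen after seeing the data. In the simulated data, unchanged genes made up 12.18% and 12.25% of DESeq2 calls with siRagC1 and siRagC2, against 3.977% and 5.978% of edgeR calls. The simulated libraries lacked the structure between the real libraries, so these shares can be too low for the real data. Counts of higher and lower genes below are given for siRagC1, siRagC2 and both siRNAs against siCtrl, and the causes were not tested unless stated. Without a filter they were 596 and 203, 549 and 294, and 264 and 97. With DESeq2 they were 429 and 362, 483 and 525, and 217 and 193. With the replicate number as a block they were 503 and 361, 560 and 426, and 278 and 173. For siCtrl and siRagC1, a library's own number was the best match in 4 of 6 cases before the code series was removed (number 4, 0.0765). Without the series term the counts were 6 and 1, 12 and 7, and 3 and 1. With the compared groups alone they were 100 and 26, 138 lower with siRagC2, and 70 and 11. With D1103 alone they were 343 and 211, 618 and 531, and 175 and 114, and with D1221 alone 0 and 1, 1 and 0, and 0 and 0. With effects fitted per series they were 43 and 14, 113 and 117, and 12 and 6 for D1103, and 3 and 1, 2 and 1, and 1 and 1 for D1221. By construction, an adjusted p under 0.01 gave fewer, 46 and 8, 63 and 35, and 25 and 6, as did a minimum fold of 1.2, 3 and 1, 5 and 1, and 1 and 1. Divided controls shared 4 and 1, and 6 and 2. With libraries left out, the ranges were 31 to 643 and 2 to 535, 31 to 538 and 11 to 490, and 12 to 222 and 2 to 152. Between the siRNAs, the counts were 155 and 64 without a filter, 18 and 11 with DESeq2, 134 and 97 with D1103 alone and 13 and 5 with effects fitted per series in D1103, and ranged from 0 to 290 and 0 to 229 with libraries left out. RRAGC kept its direction in all settings run and missed the threshold with siRagC2 in D1221 alone (-0.95). The mitochondrial list reversed with siRagC1 without siRagC1 replicate 4 (0.014) and missed the threshold without siCtrl replicate 6 (-0.082). With the block, the mTORC1, matrix structural and integrin lists passed with siRagC1 (adjusted p = 0.0498, 0.0492 and 0.0492; adjusted p = 0.181, 0.463 and 0.123 with an estimated correlation). Of 242 named-gene results, RRAGC aside, RLE factors left 242 on the same side of the threshold, DESeq2 211, and D1221 alone 148 of 240. Of the 92 results past the threshold, 92 missed it with D1221 alone and 84 without the series term. No result past the threshold reversed in any setting, and 7 others changed sign with D1221 alone and 14 with D1103 alone.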

Other observations

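The genes below were chosen after their values were seen, and none was tested further. Several transcripts of low level rose with both siRNAs. KCP, a secreted modulator of BMP signalling, rose from 0.473 CPM with siCtrl to 1.96 and 2.10 with siRagC1 and siRagC2 (n = 6; log2 fold changes 2.05 ± 0.23 and 2.11 ± 0.23, adjusted p = 0.000129 and 6.35e-05). ACP5, the tartrate-resistant acid phosphatase of osteoclasts, rose from 0.346 to 0.938 and 0.877 CPM (2.83-fold and 2.59-fold, adjusted p = 0.0274 and 0.0358), and SIGLEC15, a receptor of osteoclast differentiation, from 0.682 to 1.45 and 1.36 CPM (1.12 ± 0.24 and 1.01 ± 0.25, adjusted p = 0.0187 and 0.0270; higher in 5 of 6 numbers with each). GCNT3, a glycosyltransferase, rose by 1.27 ± 0.30 and 1.22 ± 0.31, and SMPDL3B, a membrane phosphodiesterase, from 2.00 to 3.32 and 4.09 CPM (0.71 ± 0.16 and 1.03 ± 0.15, adjusted p = 0.0206 and 0.00127).

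Without the number 6 libraries, a setting taken up for this paragraph after the data were seen, siRagC1 and siRagC2 differed at single genes. The histone genes H1-2, H2BC5, H2AC6 and H2BC12 were lower with siRagC1 (-0.77, -0.74, -0.70 and -0.63 in log2), as were COL1A1 (-0.92) and TGFBI (-0.48), proteins of the matrix. The interferon-stimulated genes IFI44 and OASL (0.49 and 0.50) and HAS2, a hyaluronan synthase (0.51), were higher. With number 6 included edgeR called 0 genes, so these values hold for 5 libraries per group.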
